A study of Mus musculus with 22 samples.

How the data were processed

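Primary germinal center B cells from mouse spleen were measured in 3 single-cell gene expression libraries, 3 matching single-cell immunoglobulin libraries and 16 bulk heavy-chain libraries. Groups were taken from the sample titles: NP (2 libraries) and OVA (1 library) for single cells, and the letters n and p at days 7 and 13 (4 libraries each) for the bulk data. Per the submitters' processing notes, Cell Ranger and the mouse genome build mm10 were used for the single-cell data; versions, filters and the tools behind the bulk sequences were not given in the sources used here. The single-cell libraries were sequenced on a NovaSeq and the bulk libraries on a MiSeq, per the labels' protocols.

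The deposited gene table holds UMI counts per gene and cell, whole numbers that the authors did not normalize, for 8873 cells and 14407 genes of all 3 libraries. In its values each gene was detected in at least 3 cells and each cell had at least 498 UMIs. The deposited immunoglobulin contig tables give V, J and constant gene calls, CDR3 sequences and UMI counts per contig. The deposited bulk table gives a sequence per row with its V and J calls and V identity, a percent of aligned V bases equal to germline, computed by the authors per the file headers. It gives no number of reads or molecules per sequence, and no CDR3 or isotype, which were therefore derived here: the CDR3 from the end of framework 3 and the J alignment, and the isotype by matching the bases after J to constant region starts with at most 1 mismatch. An in-frame CDR3 was found in 8151 of 8520 sequences (95.7%), and 23 had no isotype call; IgM made up 64.6% and IgG1 28.6%. V mutations were counted over the aligned V segment.

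Cells were kept with at least 500 detected genes and at most 10% mitochondrial UMIs; this removed cells with more than 10% in 1028, 246 and 588 cases and with under 500 genes in 207, 123 and 77 cases (NP 1, NP 2 and OVA 1), leaving 69.1%, 83.1% and 79.4%. The Scrublet method of scanpy marked 0, 8 and 0 cells as doublets, which are also left out. These are too few for the caller to have worked, so doublets that it missed were not removed. Cells with more than 1 productive heavy chain were left out as an alternative. Of the gene symbols, 13455 matched RefSeq symbols or synonyms of GRCm38.p6, the assembly behind mm10, from which coordinates were taken. For all tests 226 immunoglobulin genes were removed, since receptor genes define several groups.

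Clustering (scanpy 1.11.5, leidenalg 0.10.2, numpy 2.4.6, Python 3.11.15) used 2000 variable genes, scaled within each library, 30 principal components, 15 neighbours and a resolution of 1.0, with 0.5 as the alternative. The metabolic lists (218 genes) were left out of clustering so that they could be compared between clusters. A cluster took the class with most markers (at least 3) among 50 genes of largest fold detected in at least 10% of its cells. Cluster 3 stays unnamed for its leading genes. Tests restricted to LZ-like or DZ-like cells used the classes at resolution 0.5, where the larger LZ-like cluster shared leading genes with cluster 3. Shares of cells with a Myc UMI were computed after thinning each cell to 2500 UMIs, since depth differs between libraries and between clusters; the Myc comparison itself used the thinned counts, with Myc removed.

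Cells are not replicates, so raw counts were summed per library and arm and tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood test, with TMM normalization, filterByExpr and Benjamini-Hochberg adjustment, at an adjusted threshold of 0.05. Within-library comparisons had library as a block. SE is the absolute log2 fold divided by the square root of F. DESeq2 1.42.0 was the alternative test. The arms were clusters 1, 3 and 10, which the marker count gave as LZ-like, against DZ-like cells, Myc-detected against undetected cells, cells of clones with at least 2 cells against cells seen once, switched against IgM or IgD cells, IGHV1-72 lambda cells against other NP cells, and NP against OVA libraries. Receptor classes came from the productive heavy chain with the most UMIs. In that first comparison the adjustment covered all genes and only list genes are reported, because the other genes shaped the clusters. Sums without replicates in 1 arm, or with 1 residual degree of freedom, rest on few values.

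Lists of genes were fixed before the data were examined, as were the comparisons, the tests, the cluster markers, the rule for named genes and most alternatives: nuclear-encoded OXPHOS, mitochondrially encoded OXPHOS, TCA cycle, glycolysis, MYC targets, mTORC1 and amino acid metabolism, cytosolic ribosome, G2 and M phase, S phase, receptor, CD40 and NF-kB response, antigen presentation, germinal center factors, memory and naive B cell, plasma cell, hypermutation and switching, apoptosis, interferon response, unfolded protein and heat shock, dissociation response, and markers of T cells, NK cells, myeloid cells and erythroid cells. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, which asks whether list genes moved more than other genes, and again with an estimated correlation, which is wide with so few sums. Adjusted values are over the lists of a comparison. Named genes are the 10 largest rises and 10 largest falls past the threshold with an average log2 CPM of at least 4, the members of each named list with the smallest p-values, and Myc, Cxcr4 and Cd83. A few genes that the rule names are not reported here. For V genes, all that passed and the 3 most used per group are named.

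Bulk V genes were counted as distinct rearrangements (same V, J and CDR3 nucleotide sequence) per library, so that the depth and amplification of a molecule do not weigh, and the 16 libraries were fitted together with a shared dispersion; with 15 of 94 V genes past filterByExpr, no dispersion trend was fitted. Switched percent, mutations, CDR3 length, evenness and the share of the 10 largest clones were compared by two-sided exact permutation tests over 70 arrangements, with 25 tests in the family. At day 7 the replicate numbers were taken to pair n with p, from rearrangements that same-numbered libraries share, as cells of the same animal would; exchanged molecules would give this too, and at day 13 the numbers were not taken as pairs. PCR reads without molecular counts are not independent molecules. Pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables, exact tests and plots.

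The tests were tried on simulated counts with the real means and library sizes. At a log2 fold of 1, edgeR recovered 9.28% of changed genes for NP against OVA, 93.9% for expanded clones, 90.9% for switched cells, 44.9% for the Myc comparison, 89.8% for clusters 1, 3 and 10 against DZ-like cells and 87.8% for IGHV1-72 lambda; the share of false calls was 0%, 3.55%, 3.73%, 4.92%, 2.74% and 8.33%. Of V genes changed by a log2 fold of 1.2, 93.2% and 73.2% were recovered for p against n at days 7 and 13. Nuclear-encoded OXPHOS, raised by 0.3 on the log2 scale, was called at the preset correlation in each gene comparison. With an estimated one it was called only for expanded clones (adjusted p = 0.00500), switched cells (0.0133) and clusters 1, 3 and 10 against DZ-like cells (0.0118). At the preset one 1 of 22 lists not raised was also called for NP against OVA. False list calls in the real data were not tested.

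Alternatives covered test, normalization, low-count filter, cell filter, thinning, cell classes, clustering resolution, clone definition, isotype, library block, replicate number as a block in bulk data, and leaving out each library. Those added after the data were seen, named as such, include splits that part each day 7 bulk pair or the arms of each single-cell library, and sign flips within numbers for the bulk and single-cell overlap.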

Results

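Germinal centers are sites in lymphoid tissue where B cells mutate their antibody genes and compete for help from T cells. The series measured such B cells from the spleens of C57BL/6 mice, immunized with the hapten-carrier conjugate NP-KLH or with ovalbumin (OVA) in alum with lipopolysaccharide. Droplet-based 5' single-cell RNA sequencing gave 3 libraries, of which NP 1 and NP 2 held germinal center B cells that bind NP, sorted on day 13, and OVA 1 held total germinal center B cells of OVA-immunized mice. The day of the OVA sort was not given in the sources used here. An immunoglobulin library from the same cells accompanied each of the 3. Bulk sequencing of immunoglobulin heavy chains from OVA-binding germinal center B cells gave 16 libraries, with 4 each for the letters n and p at day 7 and at day 13. The labels do not say what n and p stand for, so the letters are used here as names only.

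The gene table held 3765 cells and 20533741 transcript counts (unique molecular identifiers, UMIs) for NP 1, 2104 cells and 16161435 UMIs for NP 2, and 3004 cells and 21412501 UMIs for OVA 1. The median was 4354, 6829 and 5899 UMIs per cell. After a filter on detected genes and mitochondrial UMIs, 2600, 1748 and 2385 cells remained, with medians of 5892, 8038.5 and 7443 UMIs. A productive heavy chain was read in 1947, 1541 and 2015 cells. The bulk libraries held 285 to 1000 sequences each and 8520 in all, which reduced to 179 to 610 distinct heavy-chain rearrangements per library. Nothing in the labels says that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. Intervals on shares of a single library are exact Clopper-Pearson intervals at 95%, and they cover counting error only.

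Receptor usage in the single-cell immunoglobulin libraries differed between the immunizations. IGHV1-72, the V gene of the canonical anti-NP antibody in this strain, was used by 56.9% (54.6 to 59.1) of NP 1 cells and 62.6% (60.2 to 65.0) of NP 2 cells, against 8.04% (6.89 to 9.31) of OVA 1 cells. The lambda light chain, its usual partner, was carried by 73.2% (71.2 to 75.2), 77.5% (75.3 to 79.6) and 3.63% (2.85 to 4.56). Among IGHV1-72 cells lambda reached 96.0% (94.6 to 97.1) and 96.4% (95 to 97.5) in the NP libraries and 1.26% (0.153 to 4.47) in OVA 1. Cells with other V genes were also often lambda-positive in the NP libraries, at 43.8% (40.4 to 47.3) and 45.7% (41.6 to 50.0), and rarely in OVA 1, at 3.84% (3.0 to 4.84). Tyrosine at the fourth amino acid of the heavy-chain CDR3, known from anti-NP antibodies, was read in 73.2% (70.5 to 75.8) and 73.2% (70.2 to 75.9) of IGHV1-72 cells in NP 1 and NP 2, and in 0.617% (0.0156 to 3.39) in OVA 1. IGHV14-3 was the next to follow the NP libraries, at 10.3% (9.01 to 11.8) and 9.54% (8.12 to 11.1) against 0.447% (0.204 to 0.846). IGHV2-5 took 8.49% (7.31 to 9.79) of OVA 1 cells, 0.0514% of NP 1 cells and 0 of 1541 NP 2 cells, where a floor of 3 cells would be 0.195%. With 1 OVA library, and a different gate for it, the antigen and the gate cannot be told apart.

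Class-switched receptors were found in 54.9% (52.6 to 57.1), 56.1% (53.6 to 58.6) and 48.2% (46.0 to 50.4) of cells in NP 1, NP 2 and OVA 1. IgG2c and IgG3 were more frequent in the NP libraries (14.4% and 17.7% for IgG2c, 13.8% and 12.9% for IgG3) than in OVA 1 (7.00% and 2.24%). IgG1, at 15.1% and 11.9% against 19.6%, was more frequent in OVA 1. Cells of clones seen at least 2 times made up 48.3% (46.1 to 50.6), 45.2% (42.7 to 47.8) and 55.8% (53.6 to 58.0), where a clone is a set of cells with the same V gene, J gene and CDR3 nucleotide sequence. The largest clones held 37 cells in NP 1 (IGHV14-2), 31 in NP 2 (IGHV1-72) and 43 in OVA 1 (IGHV2-5). NP 1 and NP 2 shared 15 rearrangements, and all 15 used IGHV1-72; OVA 1 shared 0 with either.

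**Figure D1:**
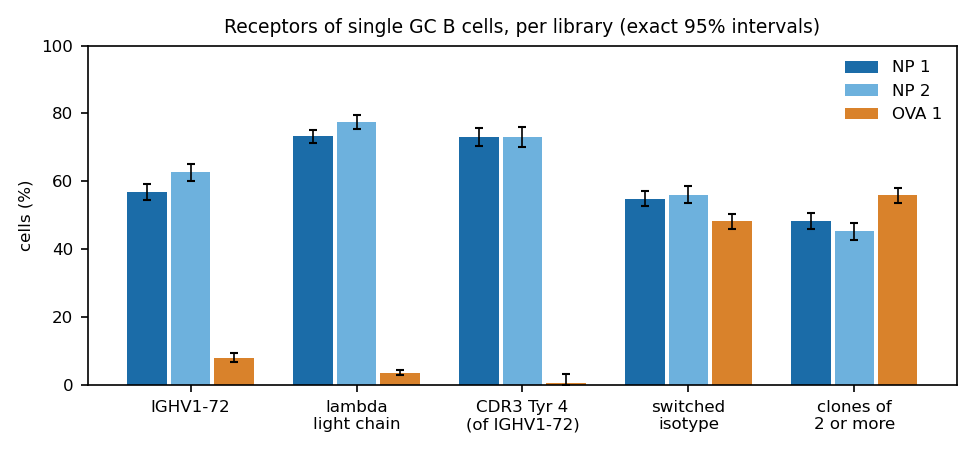
Percent of cells with a productive heavy chain in each single-cell library (for the tyrosine panel, of cells with IGHV1-72) that use IGHV1-72, carry a lambda light chain, have tyrosine at CDR3 position 4, are class-switched, or belong to a clone of at least 2 cells; bars are shares and error bars exact 95% intervals. IGHV1-72 lies at 56.9% and 62.6% in the NP libraries and at 8.04% in OVA 1.

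Clustering of the passing cells without immunoglobulin genes and without the metabolic gene lists gave 16 clusters. By markers fixed in advance, clusters 1 and 10 were light zone-like (LZ-like), clusters 2, 7 and 9 dark zone-like (DZ-like), cluster 11 resembled memory or naive B cells, cluster 14 myeloid cells and cluster 15 T cells; the rest stayed unnamed. Cluster 3 had 4 LZ markers, but its 10 leading genes held none of them and Cd38, a marker of memory and naive B cells, so it stays unnamed and these clusters are given by number. Cluster 1 held 12.4%, 12.2% and 12.6% of cells in NP 1, NP 2 and OVA 1, cluster 3 held 10.9%, 10.0% and 11.5%, and cluster 10 held 6.62%, 5.84% and 6.92%. DZ-like cells made up 29.1%, 28.1% and 23.1%. The memory-like cluster took 2.35% (1.80 to 3.0), 3.49% (2.68 to 4.46) and 5.87% (4.96 to 6.89). Myeloid-like cells were 0.577% (0.323 to 0.95), 0.915% (0.524 to 1.48) and 1.38% (0.954 to 1.94), and T cell-like cells 0.231% (0.0847 to 0.502), 0.744% (0.397 to 1.27) and 1.22% (0.816 to 1.74). The gates differed between the NP and OVA sorts, and these shares have no replicate test. In cluster 1, 68.4%, 71.0% and 62.9% of cells were switched, against 51.1%, 54.9% and 36.8% in cluster 3.

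The series asks about oxidative phosphorylation (OXPHOS) in selection, and metabolic genes were first compared between clusters 1, 3 and 10, grouped by the count of LZ markers, and DZ-like cells. Nuclear-encoded genes of OXPHOS, which make the respiratory chain and ATP synthase, were lower in clusters 1, 3 and 10: 64 of 77 measured members fell, 1 rose and 12 did not pass the test (1 higher and 67 lower adjusted over the list alone). Their median log2 fold was −0.42, with Atp5j at −0.91 ± 0.06 (SE), Sdhd at −1.04 ± 0.08, Cox6a1 at −0.81 ± 0.06, Cox7a2 at −0.80 ± 0.06 and Cycs, the electron carrier cytochrome c, at −0.81 ± 0.07. Of 16 genes of the TCA cycle, 14 fell (14 adjusted over the list alone; median −0.39), among them Fh1 at −0.82 ± 0.07 and Idh3g at −0.63 ± 0.07. The 13 mitochondrially encoded OXPHOS genes went the other way: 10 rose and 0 fell (11 adjusted over the list alone; median 0.22), led by mt-Nd5 at 0.44 ± 0.07 and mt-Nd4 at 0.40 ± 0.07. Cytosolic ribosomal proteins rose in 21 of 44 members and fell in 1 (20 and 1 adjusted over the list alone; median 0.15), with Rps27 at 0.60 ± 0.08, Rpl37 at 0.42 ± 0.08 and Rps24 at 0.42 ± 0.08. MYC targets were split, with 8 of 34 higher and 19 lower, Ptma at −1.55 ± 0.08 and Ran, a nuclear transport GTPase, at −1.38 ± 0.07, and, on the higher side, Myc itself at 1.55 ± 0.09, Ppan at 0.58 ± 0.07 and Mybbp1a at 0.51 ± 0.07. Among 18 genes of mTORC1 and amino acid metabolism 3 were higher and 10 lower. Ddit4, an inhibitor of mTORC1, rose by 2.62 ± 0.10 and the amino acid transporter Slc7a1 by 0.58 ± 0.10, while the serine synthesis enzyme Psat1 stood at −1.24 ± 0.08 and the sterol synthesis enzyme Idi1 at −0.91 ± 0.09. Glycolysis had 4 of 16 higher and 8 lower, with Aldoa at 0.53 ± 0.06, Tpi1 at −0.79 ± 0.06 and Gapdh at −0.66 ± 0.07.

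These values come from edgeR's quasi-likelihood test on counts summed per library and class, with library as a block, and the adjusted p was taken over all genes tested. Of 217 list genes measured, 162 passed, 47 higher and 115 lower in clusters 1, 3 and 10. Without cluster 3 it was 142 of 216, 53 higher and 89 lower. In the list test with a preset correlation, the adjusted p was 5.9e-09 for nuclear OXPHOS, 0.0196 for the TCA cycle, 0.0292 for the ribosome (0.0546 without OVA 1) and 0.0433 for mitochondrially encoded genes; it was 0.264 for MYC targets (called downward at resolution 0.5, 0.00768, and with no low-count filter, 0.0499), 0.383 for glycolysis and 0.385 for mTORC1. With an estimated correlation the adjusted p was 0.567, 0.513, 0.765 and 0.719 for the first 4, and no list was called. Without cluster 3 nuclear OXPHOS was still called at the preset correlation (median −0.30, adjusted p = 2.8e-06), but the TCA cycle (−0.30), the ribosome (0.11) and mitochondrially encoded genes (0.17) were not, each with an adjusted p of 0.0524. The medians of MYC targets and glycolysis turned from −0.18 to 0.07 and from −0.16 to 0.03. Clusters 1, 3 and 10 were shallower, with median UMIs of 4654, 6453 and 6262 against 7809, 10919 and 11431 in DZ-like cells. Cxcr4 and Cd83 helped to name the clusters and are not compared here.

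**Figure D2:**
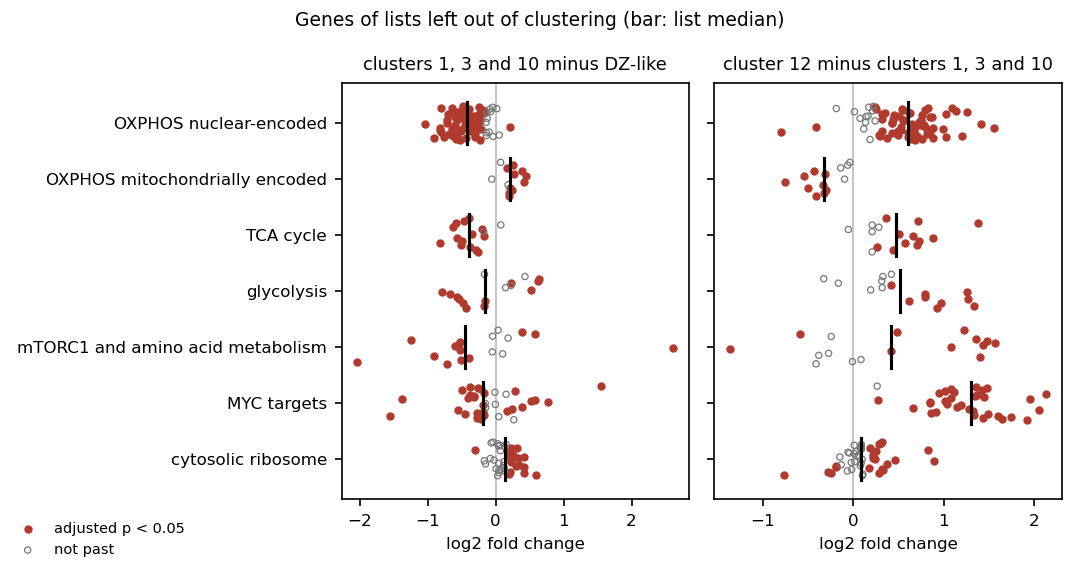
Log2 fold change of every measured member of the metabolic lists, clusters 1, 3 and 10 minus DZ-like cells on the left and cluster 12 minus clusters 1, 3 and 10 on the right; each point is a gene, red with an adjusted p under 0.05, and the bar is the list's median. Nuclear OXPHOS genes have a median of −0.42 on the left and 0.60 on the right.

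Myc, a transcription factor that is transiently induced in germinal center B cells receiving help, was detected in 6.03% (5.10 to 7.07), 6.27% (5.13 to 7.58) and 9.47% (8.27 to 10.8) of cells of NP 1, NP 2 and OVA 1 thinned to 2500 UMIs. For this 262, 154 and 231 shallower cells were left out. Unthinned shares were 12.4%, 16.2% and 20.4%. In the myeloid-like cluster, 0 of 8, 0 of 11 and 0 of 21 thinned cells had a Myc UMI. The exact intervals reach up to 36.9%, 28.5% and 16.1%, so that background from free RNA was not resolved. Cluster 10 had the cells most often Myc-positive among clusters 1, 3 and 10, at 28.8%, 23.8% and 29.6%.

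Cells with detected Myc carried more transcripts of the response to antigen receptor, CD40 and NF-kB signals: 22 of 27 members rose and 0 fell (25 adjusted over the list alone; median log2 fold 1.05), including the NF-kB inhibitor gene Nfkbia at 1.33 ± 0.09 and Il4i1 at 1.35 ± 0.09. Cd83, a light zone marker of the same list, rose by 0.99 ± 0.08. The largest rises were in the cell cycle gene Ccnd2 (2.38 ± 0.27), the chemokine gene Ccl5 (2.12 ± 0.23), Nfkbid (2.07 ± 0.17), the AP-1 factor Batf (2.03 ± 0.23), and Tagap (1.73 ± 0.29). They also included Tnfaip3 (1.53 ± 0.24), Tnfsf9 (1.48 ± 0.19), Rilpl2 (1.43 ± 0.25), Egr1 (1.40 ± 0.16) and the adhesion gene Icam1 (1.37 ± 0.13). MYC targets other than Myc rose in 15 of 33 members (21 adjusted over the list alone; median 0.37), with the chaperone gene Hspe1 at 0.56 ± 0.09 and the nucleolar genes Gnl3 at 1.05 ± 0.18, Npm1 at 0.33 ± 0.06 and Ncl at 0.40 ± 0.08. In the hypermutation and switching list 2 of 15 members were lower and 1 higher (2 and 1 adjusted over the list alone), among them Apobec1 at −0.77 ± 0.15 and the uracil glycosylase gene Ung at 0.85 ± 0.18. Cxcr4 stood at −0.58 ± 0.19 (adjusted p = 0.124). Neutrophil and macrophage transcripts were nearly absent from these cells: Lcn2 had 0 UMIs against 316, a level at least 8.32-fold lower by a floor of 3 counts over the group. With the same direction, Lyz2 had 1 against 827 UMIs (ratio 65.3, counting interval 11.7 to 2582), Ltf 1 against 242 (19.1, 3.40 to 758) and Ngp 2 against 1220 (48.2, 13.3 to 398). S100a9 (4 against 4042), S100a8 (4 against 3348) and Camp (6 against 1080) also fell, and so did the mitotic genes Kif22 (−1.25 ± 0.34) and Cdc20 (−1.0 ± 0.21) and Rrm2b (−1.07 ± 0.23).

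Of the other lists in these cells, nuclear OXPHOS had 0 of 77 genes higher and 1 lower, Cox7a2l at −0.41 ± 0.09 (0 and 1 adjusted over the list alone; median −0.04); 0 of 13 mitochondrially encoded genes and 0 of 16 TCA cycle genes passed. With all UMIs kept in place of thinned cells, nuclear OXPHOS (median 0.13, adjusted p = 7.7e-11), the TCA cycle (0.11, 0.00332) and the hypermutation list (0.19, 0.0417) passed upward. Glycolysis had 1 of 15 higher (2 adjusted over the list alone), Ldha at 0.34 ± 0.08, and mTORC1 1 of 17 (4 and 1 lower adjusted over the list alone), Shmt2 at 0.55 ± 0.14. Heat shock genes had 3 of 11 higher (6 adjusted over the list alone), Hspe1, Hspd1 at 0.57 ± 0.12 and Hsp90ab1 at 0.24 ± 0.05. The dissociation response had 3 of 11 (4 adjusted over the list alone), Junb at 1.00 ± 0.10, Egr1 and Ier2 at 1.29 ± 0.20. G2 and M phase genes had 2 of 49 lower (5 adjusted over the list alone; median −0.26), Cdc20 and Mki67 at −0.53 ± 0.11. In LZ-like cells alone this list passed upward, with a median of 0.19 (adjusted p = 0.00148) and Mki67 at 0.25. S phase genes had 2 of 35 higher (2 adjusted over the list alone), Ung and Cdca7 at 0.51 ± 0.14. Among memory and naive genes 3 of 17 were higher (3 and 1 lower adjusted over the list alone), among them Fcer2a at 0.77 ± 0.09 and Ccr6 at 1.47 ± 0.34. Germinal center factors had 2 of 18 lower (5 adjusted over the list alone), Foxo1 at −0.58 ± 0.15 and Gcsam at −0.54 ± 0.14. Plasma cell genes had 2 of 12 higher and 1 lower (3 and 1 adjusted over the list alone), Hspa5 at 0.58 ± 0.09, Irf4 at 1.31 ± 0.27 and Mzb1 at −0.36 ± 0.07.

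In all, 152 of 9200 genes passed edgeR's quasi-likelihood test with library as a block, 109 higher and 43 lower in Myc-detected cells. In the list test the adjusted p was 1.0e-88 for the receptor and NF-kB list, 1.7e-31 for MYC targets, 4.1e-30 for myeloid markers (4 of 7 lower, 5 adjusted over the list alone), 4.4e-10 for dissociation, and 8.4e-09 for heat shock. It was 5.5e-07 for G2 and M phase, 0.000398 for S phase, 0.00162 for memory genes, and 0.00846 for germinal center factors. Mitochondrially encoded genes had an adjusted p of 0.0198 (median −0.07), and it was 0.0203 for plasma cell genes, 0.0270 for mTORC1 (median 0.22), 0.0270 for nuclear OXPHOS and 0.0290 for glycolysis (median 0.19). With an estimated correlation the adjusted p of these lists lay between 0.153 and 0.677, so no list was called. Calls also ended without NP 1 for S phase (0.246), mitochondrially encoded (0.105), plasma cell (0.0985), mTORC1 and glycolysis genes (0.158 each), without NP 2 for mitochondrially encoded (0.805), glycolysis (0.0771) and mTORC1 genes (0.0599), and without OVA 1 for nuclear OXPHOS (0.771), memory (0.179) and plasma cell genes (0.0581). The memory list turned downward in LZ-like (median −0.17) and DZ-like cells alone (−0.32). The count was 71 without NP 1, 55 by DESeq2, 3 without the library block, 4 in DZ-like cells alone and 83 under the stricter cell filter. With all UMIs kept in place of thinned cells it was 2383, of which 133 were among the 152. Without the myeloid-like and other small clusters S100a9 stood at 0.13 and S100a8 at 0.22.

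Expanded clones were compared with clones seen once within each library. Genes of G2 and M phase were higher in expanded clones: 28 of 50 rose and 0 fell (37 adjusted over the list alone; median log2 fold 0.21), with the cyclin gene Ccnb1 at 0.56 ± 0.07, Cdc20 at 0.39 ± 0.05, Birc5 at 0.35 ± 0.04 and Hmgb2 at 0.23 ± 0.02. S phase genes rose in 10 of 35 (23 adjusted over the list alone; median 0.13), among them the replication genes Mcm5 at 0.17 ± 0.04 and Rrm1 at 0.19 ± 0.05. In DZ-like cells alone the S phase list passed downward, with a median of −0.0796 (adjusted p = 0.000536). Memory and naive B cell genes were lower, with 12 of 17 past the test (13 adjusted over the list alone; median −0.60): the trafficking regulator Klf2 at −1.96 ± 0.10, Ccr6 at −1.74 ± 0.17 and Cd38 at −0.81 ± 0.10. The memory-like cluster made up 0.750%, 0.972% and 2.11% of expanded cells in NP 1, NP 2 and OVA 1, against 5.61%, 5.93% and 13.1% of cells seen once. Plac8 (mm10 chromosome 5, 100551589 to 100572253) fell the most, by 3.41 ± 0.13, followed by Ifi203 (−1.37 ± 0.12), Lgals9 (−1.10 ± 0.11), Sub1 (−0.96 ± 0.08), Snn (−0.92 ± 0.09), Capg (−0.91 ± 0.08), Ephx1 (−0.88 ± 0.12), Mndal (−0.85 ± 0.10) and Ly6d (−0.83 ± 0.05). Other large rises were in Lrrc49 (0.44 ± 0.10), C330027C09Rik (0.43 ± 0.11), Serpinf1 (0.42 ± 0.11), Sgo1 (0.41 ± 0.10), Cep55 (0.39 ± 0.07), Ddah2 (0.38 ± 0.08), B9d1 (0.36 ± 0.11) and Dhcr7 (0.36 ± 0.10). Sgo1 (−0.64), Cep55 (−0.23) and Ccr6 (0.09) turned in LZ-like cells alone, none past the test.

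The receptor and NF-kB list was lower in expanded clones, with 16 of 28 members (17 adjusted over the list alone; median −0.21), among them Ccr7 at −2.56 ± 0.28, Il4i1 at −0.36 ± 0.04, Cd83 at −0.23 ± 0.04 and Nfkbia at −0.24 ± 0.04. In LZ-like cells alone the list turned upward (median 0.05, adjusted p = 0.267), with Cd83 at 0.02 and Nfkbia at 0.01. Antigen presentation fell in 9 of 15 (12 adjusted over the list alone; median −0.14), with the MHC class II genes H2-Aa at −0.23 ± 0.02 and H2-Oa at −0.31 ± 0.04 and Cd74 at −0.14 ± 0.02. Lower too were 20 of 44 ribosomal genes (31 adjusted over the list alone; median −0.06), such as Rps27 at −0.13 ± 0.02 and Rps24 at −0.13 ± 0.02. So were 5 of 12 interferon genes (6 adjusted over the list alone; median −0.35), such as Ifi27l2a at −0.36 ± 0.04 and Zbp1 at −0.43 ± 0.12. Of 10 dissociation genes 4 were lower (5 adjusted over the list alone; median −0.18), such as Ier2 at −0.51 ± 0.08 and Junb at −0.23 ± 0.04. Of the metabolic lists, mTORC1 had 7 of 18 higher and 1 lower (9 and 1 adjusted over the list alone; median 0.10), with Idi1 at 0.34 ± 0.06, Insig1 at 0.35 ± 0.08 and Ddit4 at −0.40 ± 0.07. Nuclear OXPHOS had 1 of 77 higher (1 adjusted over the list alone), the ATP synthase gene Atp5a1 at 0.11 ± 0.03, and a median of 0.05. No mitochondrially encoded (0 of 13) or TCA cycle gene (0 of 16) passed, and MYC targets had 2 of 34 higher, Ptma at 0.12 ± 0.02 and Ran at 0.11 ± 0.03, and 1 lower, Srm at −0.22 ± 0.06. The MYC target list was not called (adjusted p = 0.0559) but passed upward in 9 alternatives, among them LZ-like cells alone (median 0.13, 2.0e-08), thinned cells (0.08, 0.000397) and without OVA 1 (0.06, 8.9e-05). The plasma cell list (0.0548) passed downward in 6 alternatives and the TCA cycle (0.0706) upward in 1. Among myeloid markers 3 of 7 were lower, Lyz2 at −3.24 ± 0.35, Tyrobp at −1.75 ± 0.28 and Fcer1g at −2.29 ± 0.38; the list's median was 0.04, its mean −0.94 and its test lower. This test pointed upward in LZ-like (median 0.27) and DZ-like cells alone (0.07) and without the myeloid-like and other small clusters (0.10), and the call ended without NP 2 (0.865) or OVA 1 (0.618). Bcl2, which opposes apoptosis, fell by 1.31 ± 0.19, and the plasma cell list had 0 of 13 higher and 2 lower, Pdia4 at −0.68 ± 0.08 and Ssr4 at −0.18 ± 0.04. Myc (−0.18 ± 0.07, adjusted p = 0.156) and Cxcr4 (0.10 ± 0.06, 0.497) did not pass.

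By edgeR's quasi-likelihood test with library as a block, 574 of 10410 genes passed, 199 higher and 375 lower in expanded clones. List tests gave an adjusted p of 3.8e-38 for G2 and M phase, 5.1e-27 for memory genes, 4.5e-19 for the receptor and NF-kB list, 1.2e-16 for antigen presentation, 2.7e-16 for S phase, 4.1e-13 for the ribosome, 6.5e-07 for interferon, 7.4e-07 for dissociation, 9.9e-06 for nuclear OXPHOS, 0.000168 for mTORC1 and 0.0122 for myeloid markers. With an estimated correlation the adjusted p lay between 0.133 and 0.381, so no list was called. Without NP 1, NP 2 or OVA 1 the count was 370, 366 and 254; it was 69 by DESeq2, 186 without the memory-like and other small clusters, 1 in LZ-like cells alone and 7 in DZ-like cells alone. Without the library block, edgeR called 0 genes (93 at an unadjusted p under 0.05).

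Class-switched cells were compared with IgM cells in the same libraries. Slpi, a secreted protease inhibitor (mm10 chromosome 2, 164354070 to 164356507), had the largest rise, at 1.53 ± 0.08, followed by the transcription factor Tox at 1.14 ± 0.08, Parm1 at 1.04 ± 0.16, Fos at 0.80 ± 0.07, and Serpinf1 at 0.76 ± 0.11. Next came Lmo2 at 0.72 ± 0.05, Fscn1 at 0.68 ± 0.09, Rgs1 at 0.65 ± 0.06, Tox2 at 0.60 ± 0.12 and Plpp1 at 0.56 ± 0.10. Memory and naive B cell genes were lower: 9 of 17 fell and 1 rose (9 and 1 adjusted over the list alone; median −0.49), including Klf2 at −1.62 ± 0.10, Cd38 at −1.12 ± 0.12 and Ccr6 at −1.61 ± 0.17. The memory-like cluster held 0.994%, 1.37% and 1.67% of switched cells in NP 1, NP 2 and OVA 1, and 6.08%, 6.95% and 11.9% of IgM cells. Plac8 fell by 3.53 ± 0.15, Ephx1 by 1.2 ± 0.14, Ly6d by 1.13 ± 0.06, Ifi203 by 1.13 ± 0.13, Grap2 by 1.04 ± 0.12, Lmo4 by 0.91 ± 0.07, Cd72 by 0.89 ± 0.07 and Ms4a4c by 0.86 ± 0.08.

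Of the metabolic lists in switched cells, glycolysis had 3 of 16 members higher (9 adjusted over the list alone; median 0.11), Ldha at 0.16 ± 0.04, Pgam1 at 0.14 ± 0.04 and Tpi1 at 0.13 ± 0.04. In the mTORC1 list 4 of 18 were higher and 1 lower (6 and 1 adjusted over the list alone), such as the sterol genes Sqle at 0.42 ± 0.06 and Idi1 at 0.32 ± 0.06. MYC targets had 2 of 34 higher (2 adjusted over the list alone), Ldha and Eif4a1 at 0.12 ± 0.03. These 3 lists passed the list test at the preset correlation and did not with an estimated one (adjusted p = 0.601 each). The test of MYC targets turned downward with IgG1 cells alone (median 0.01, adjusted p = 0.814), and the call ended without NP 1 (0.0765). Nuclear OXPHOS had 0 of 77 past the test (median 0.00) and mitochondrially encoded genes 0 of 13. In LZ-like cells alone nuclear OXPHOS passed the list test upward (median 0.05, adjusted p = 0.00306) and mitochondrially encoded genes downward (−0.06, 0.00965), the latter also in DZ-like cells alone (−0.04, 0.0498). In the TCA cycle list 1 of 16 members was higher, Cs at 0.15 ± 0.04, and 1 lower, Suclg2 at −0.36 ± 0.06. Interferon genes were lower in 3 of 11 (6 adjusted over the list alone; median −0.39), Ifi27l2a at −0.81 ± 0.05, Irf7 at −0.35 ± 0.08 and Usp18 at −0.94 ± 0.27. The dissociation list had 6 of 10 higher and 3 lower (6 and 4 adjusted over the list alone), Fosb at 0.99 ± 0.15 and Dusp1 at 0.41 ± 0.07. Myc (−0.09 ± 0.08, adjusted p = 0.666), Cxcr4 (−0.02 ± 0.06, 0.920) and Cd83 (−0.05 ± 0.04, 0.602) did not pass. The germinal center list had 3 of 18 higher (6 and 3 lower adjusted over the list alone), Id3 at 0.22 ± 0.04, Mef2b at 0.19 ± 0.03 and S1pr2 at 0.22 ± 0.04. The receptor and NF-kB list went both ways, with 5 of 28 higher and 4 lower (7 and 4 adjusted over the list alone), Icam1 at 0.30 ± 0.05, Bhlhe40 at −0.81 ± 0.11 and Ccr7 at −1.96 ± 0.31. In LZ-like cells alone that list passed downward, with a median of −0.14 (adjusted p = 8.7e-05). In the apoptosis list 1 of 14 members was lower, Bcl2 at −1.33 ± 0.20, and 2 higher (4 higher and 2 lower adjusted over the list alone), among them the cell death gene Bid at 0.18 ± 0.05.

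In this comparison 551 of 10499 genes passed edgeR's quasi-likelihood test with library as a block, 213 higher and 338 lower in switched cells. The list test's adjusted p was 2.4e-20 for memory genes, 1.2e-07 for interferon, 1.3e-05 for glycolysis, 0.00190 for mTORC1, 0.00285 for dissociation, 0.00448 for MYC targets and 0.0411 for the ribosome (0 of 44, median −0.03). Without NP 2 it was 0.148 for the ribosome and for dissociation, and the ribosome turned without OVA 1 (median 0.00, 0.789) and in DZ-like cells alone. With an estimated correlation the adjusted p was 0.951 for the ribosome and 0.601 for the other 6. It was 0.0997 for germinal center factors (0.0398 without NP 1) and 0.900 for the receptor list and for nuclear OXPHOS. Without NP 1 the count was 225 and without OVA 1 it was 277. DESeq2 called 98, the cells outside the memory-like and other small clusters 338, LZ-like cells alone 293 and DZ-like cells alone 78. Without the library block edgeR called 0 (232 at an unadjusted p under 0.05).

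Within the NP libraries, cells with the canonical receptor (IGHV1-72 with lambda) were compared with all other NP cells. The largest rises were in Hist1h3e at 0.79 ± 0.10, Hist2h2bb at 0.77 ± 0.15, Hist1h2af at 0.66 ± 0.16, Hist1h1a at 0.60 ± 0.11, Hist1h2ab at 0.52 ± 0.12, Hist1h2ae at 0.47 ± 0.08, Hist1h1d at 0.45 ± 0.09 and Hist1h1b at 0.39 ± 0.07. In LZ-like cells alone Hist1h2ae stood at −0.52 and Hist1h1b at −0.36, neither past the test. Reads of near-identical histone genes can be shared, so each single value is uncertain. Nedd4 (0.39 ± 0.10) and the cohesin acetyltransferase Esco2 (0.37 ± 0.08) also rose. S phase genes had 2 of 35 higher (10 adjusted over the list alone; median 0.12), Mcm6 at 0.21 ± 0.05 and Rrm2 at 0.21 ± 0.05. G2 and M phase had 2 of 50 (3 adjusted over the list alone; median 0.06), Top2a at 0.24 ± 0.05 and Hmgb2 at 0.11 ± 0.03, but in DZ-like cells alone the list passed downward (median −0.0180, adjusted p = 0.0247). The largest fall was in Gm30211, at −1.72 ± 0.06, a long noncoding RNA on mm10 chromosome 6 (70729213 to 70751690) that lies next to the kappa constant gene Igkc (70726435 to 70726754), where counts of neighbours may be split. Memory and naive genes fell in 6 of 17 (1 higher and 11 lower adjusted over the list alone; median −0.55), among them Klf2 at −1.23 ± 0.14, Cd55 at −0.85 ± 0.17 and Cd38 at −0.55 ± 0.14. Memory-like cells were 1.22% and 1.04% of canonical cells in NP 1 and NP 2, and 5.73% and 8.04% of the others. Capg (−0.85 ± 0.13), 2010309G21Rik (−0.85 ± 0.14), Snn (−0.64 ± 0.12), Ly6d (−0.51 ± 0.06), Irf1 (−0.49 ± 0.12), Batf (−0.47 ± 0.10) and Sub1 (−0.47 ± 0.10) fell as well.

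Among the other lists between these receptors, antigen presentation had 2 of 15 lower (6 adjusted over the list alone), Cd74 at −0.08 ± 0.02 and Icosl at −0.34 ± 0.10. The receptor and NF-kB list had 2 of 28 (1 higher and 5 lower adjusted over the list alone), Batf and Ccr7, the latter with 7 UMIs against 53. Nuclear OXPHOS had 0 of 77 past the test (median 0.02) and was not called as a list (adjusted p = 0.0872), but it passed upward with no low-count filter (0.00711), thinned cells (0.0361) and up to 20% mitochondrial UMIs (0.00732). Myc (−0.06 ± 0.10), Cxcr4 (0.11 ± 0.08) and Cd83 (−0.06 ± 0.05) did not pass. By edgeR's test with library as a block and 1 residual degree of freedom, 73 of 10193 genes passed. Higher were 29 (1 with thinned cells) and lower 44 (24). The list test's adjusted p was 2.4e-21 for memory genes, 4.4e-15 for S phase, 1.0e-06 for antigen presentation, and 4.1e-05 for the receptor list. It was 0.000671 for the ribosome (0 of 44, median −0.02) and for G2 and M phase, 0.00992 for erythroid markers (1 of 3 higher, Hbb-bs at 0.90 ± 0.19) and 0.0117 for plasma cell genes (0 of 13, median −0.10). With an estimated correlation the adjusted p was 0.768 for the ribosome and 0.658 for the other 7. The memory, receptor, ribosome, erythroid and plasma cell lists turned in LZ-like cells alone, none past the test, as did Klf2 (0.76) and Cd55 (0.30). DESeq2 called 4 genes, LZ-like cells 1, DZ-like cells 10, and cells outside the memory-like and other small clusters 18, with Klf2 at 0.37. Without the library block edgeR called 0 (61 at an unadjusted p under 0.05).

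Between the NP and OVA libraries, where the single OVA library is assumed to vary like the NP pair (1 residual degree of freedom), the genes that stood furthest apart were sex-linked. Xist, the noncoding RNA of the inactive X chromosome (mm10 chromosome X, 103460373 to 103483233), had 0 UMIs in the passing NP cells and 14106 in OVA 1, at least 7753-fold lower by a floor of 3 counts over the group. The Y-linked genes Ddx3y (chromosome Y, 1260715 to 1286628) and Eif2s3y (chromosome Y, 1010562 to 1049134) had 2326 and 3180 UMIs in NP and 0 in OVA 1, at least 470-fold and 643-fold higher. The labels give male mice for every library. Of 13 mitochondrially encoded OXPHOS genes 4 passed, higher in NP (6 adjusted over the list alone; median 0.58), mt-Nd6 at 1.71 ± 0.30, mt-Nd3 at 1.66 ± 0.33, mt-Nd1 at 1.44 ± 0.33 and mt-Atp6 at 1.18 ± 0.33. The list took 5.33%, 4.15% and 3.11% of UMIs in NP 1, NP 2 and OVA 1, so that NP 2 lay between NP 1 and OVA 1, and the spread between libraries is not separated from the groups. Nuclear OXPHOS (0 of 77, median 0.03), the TCA cycle (0 of 16), glycolysis (0 of 17), MYC targets (0 of 34, median 0.06), S phase (0 of 35), G2 and M phase (0 of 50) and the ribosome (0 of 44) had no member past the test. Under the stricter cell filter the lists of G2 and M phase (median 0.28, adjusted p = 7.6e-05), S phase (0.23, 0.00157) and MYC targets (0.18, 0.0451) passed upward, and S phase did with thinned cells (0.20, 0.00807). The other large rises were Mir142hg (2.39 ± 0.31), Rpl13a-ps1 (1.54 ± 0.32), a pseudogene whose reads may be shared with its parent gene, Zdhhc2 (1.48 ± 0.30), Ube2s (1.46 ± 0.32) and Selenop (1.41 ± 0.27).

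Several markers of myeloid, T, NK and memory cells were lower in the NP sorts, beside the myeloid-like, T cell-like and memory-like shares given above. Myeloid markers fell in 4 of 13 (6 adjusted over the list alone), with the neutrophil genes S100a8 at −2.21 ± 0.29 and S100a9 at −2.15 ± 0.29, the complement gene C1qc with 1 against 21 UMIs (ratio 34.6, counting interval 5.57 to 1432) and Tyrobp at −0.96 ± 0.29. Outside the list Lcn2 (−2.17 ± 0.27), Ltf (−2.09 ± 0.28) and Camp (−2.07 ± 0.26) fell too. T cell markers fell in 5 of 13 (9 adjusted over the list alone), Cd3g at −1.64 ± 0.43, Cd3d at −1.35 ± 0.39, Pdcd1 with 7 against 60 UMIs and Icos with 4 against 32, while the T cell list took 0.0115%, 0.0113% and 0.0130% of UMIs in NP 1, NP 2 and OVA 1. NK cell markers fell in 1 of 6 (4 adjusted over the list alone), Ncr1 with 0 against 16 UMIs, at least 8.79-fold lower by a floor of 3 counts over the group. Among 5 erythroid markers the alpha globins Hba-a1 (108 UMIs against 0, at least 21.8-fold higher) and Hba-a2 (76 against 0, at least 15.4-fold) rose; they are near-identical copies, so their split is uncertain. The list as a whole took 0.00740%, 0.00285% and 0.00655% of UMIs in NP 1, NP 2 and OVA 1 and was not called (adjusted p = 0.118). It passed downward under the stricter cell filter (3 members, median −0.98, adjusted p = 0.00762) and upward in DZ-like cells alone (0.83, 0.00493). Memory and naive genes fell in 4 of 18 (1 higher and 13 lower adjusted over the list alone; median −0.89), Ccr6 at −2.51 ± 0.35, Hhex at −1.52 ± 0.33, Vim at −0.99 ± 0.29 and Gpr183 at −1.11 ± 0.33. The dissociation list had 4 of 12 lower and 1 higher (6 and 2 adjusted over the list alone; median −0.59), with the early response genes Fos at −1.57 ± 0.24, Dusp1 at −1.58 ± 0.24 and Jun at −1.85 ± 0.30. Interferon genes fell in 2 of 15 (4 adjusted over the list alone), Usp18 at −1.80 ± 0.51 and Isg15 at −1.03 ± 0.31. The receptor and NF-kB list fell in 3 of 29 (3 and 3 higher adjusted over the list alone; median −0.25), Bhlhe40 at −1.48 ± 0.30, Ccr7 at −1.91 ± 0.40 and Nfkb2 at −1.02 ± 0.26. The cytokine receptor Il9r (−2.85 ± 0.28), the scavenger receptor Cd36 (−2.22 ± 0.28), Lgals9 (−1.72 ± 0.29) and Capg (−1.70 ± 0.24) complete the largest falls. Myc (−0.45 ± 0.24), Cxcr4 (0.73 ± 0.28) and Cd83 (0.01 ± 0.30) did not pass.

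In edgeR's quasi-likelihood test, 238 of 11854 genes passed, 85 higher and 153 lower in NP. The list test's adjusted p was 1.1e-15 for myeloid, 1.2e-13 for T cell, 3.1e-12 for memory, 2.8e-09 for interferon, 1.6e-08 for mitochondrially encoded, 1.2e-07 for dissociation, 1.6e-06 for NK cell and 0.00929 for receptor and NF-kB genes, and the adjusted p was 0.678 for each of them with an estimated correlation. DESeq2 called 30 genes, and 76 passed in LZ-like cells alone. There were 139 in DZ-like cells alone (59.7% of them higher in NP, against 35.7% in all cells) and 134 without the memory-like, myeloid-like, T cell-like and other small clusters, with Cd3d at 0.87 and the T cell list turned upward (median 0.35, adjusted p = 0.479).

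In the bulk libraries, class-switched sequences made up 34.2% ± 1.67 (SD, n = 4) of rearrangements in n and 35.4% ± 3.99 in p at day 7, and 31.3% ± 0.735 in n and 45.2% ± 5.13 in p at day 13. At day 13 p exceeded n by 13.9 percentage points, in 4 of 4 libraries (exact permutation test, two-sided, p = 0.0286, the smallest p that 70 arrangements allow; adjusted p = 0.0918 over 25 tests), and at day 7 by 1.18 (exact p = 0.714; −0.739 without p 1 and 2.17 without p 3). From day 7 to day 13 the share changed by −2.87 points in n (exact p = 0.0286) and by 9.87 in p (exact p = 0.0571, adjusted p = 0.143). The V segment carried 1.48 ± 0.0637 mutations per rearrangement in n and 0.960 ± 0.118 in p at day 7, and 2.47 ± 0.268 and 2.09 ± 0.497 at day 13. The increase with time was 0.989 in n and 1.13 in p (exact p = 0.0286 each, adjusted p = 0.0918), and p lay below n by 0.523 at day 7 (exact p = 0.0286) and by 0.38 at day 13 (exact p = 0.20; 0.168 without p 2 and 0.571 without p 4). CDR3 length at day 7 was 12.5 ± 0.184 amino acids in n and 12.2 ± 0.109 in p (exact p = 0.0286), and at day 13 it was 12.1 ± 0.180 and 12 ± 0.213 (exact p = 0.857; p lay higher without n 4 or p 3). Clone evenness at day 7 was 0.976 ± 0.00381 in n and 0.934 ± 0.0307 in p (exact p = 0.0286) and at day 13 it was 0.929 ± 0.0966 and 0.925 ± 0.0898 (exact p = 0.80; p lay higher without n 1, n 3, n 4 or p 2). With sign flips within the day 7 pairs the p of mutations, CDR3 length and evenness was 0.125 each, the smallest that 16 arrangements allow. None of the 25 tests passed after Benjamini-Hochberg adjustment.

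**Figure D3:**
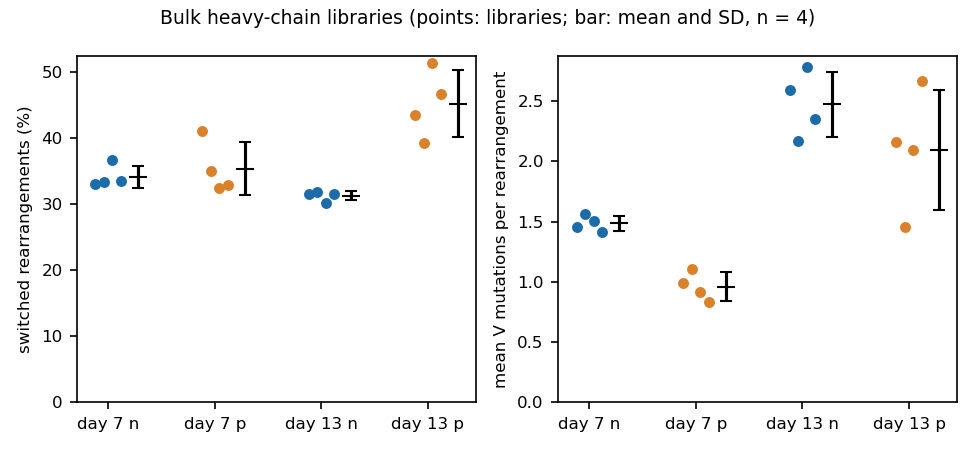
Class-switched percent of rearrangements (left) and mean V segment mutations per rearrangement (right) in each bulk library of n and p at days 7 and 13; points are libraries, bars the mean with SD, n = 4. Switched shares average 45.2% in p and 31.3% in n at day 13.

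V gene usage, counted over distinct rearrangements, differed between p and n at day 7 for 5 of the 15 V genes that passed the low-count filter. IGHV1-42 was higher in p by 1.45 ± 0.29 (log2, adjusted p = 6.3e-05), at 5.86% ± 0.820 of rearrangements against 2.01% ± 0.891. Higher too were IGHV2-3 by 1.22 ± 0.28 (0.000341; 6.76% against 2.97%), IGHV2-9-1 by 1.27 ± 0.35 (0.00308; 3.13% against 1.22%) and IGHV1-76 by 0.73 ± 0.24 (0.0126; 6.27% against 3.68%). IGHV6-3 was lower in p, at −1.02 ± 0.36 (0.0166; 1.56% against 2.89%). At day 13 no V gene passed edgeR's test (0, with 4 at an unadjusted p under 0.05 and 0 by DESeq2), where IGHV1-42 stood at 1.05 ± 0.45, IGHV1-76 at 0.75 ± 0.34 and IGHV6-3 at −1.03 ± 0.40, each with an adjusted p of 0.142. No V gene passed the test for a change of this difference between the days (lowest adjusted p = 0.844). From day 7 to day 13, IGHV1-81 rose in n by 1.08 ± 0.31 (adjusted p = 0.0110), from 2.82% to 4.81%, a call that ended with no low-count filter (0.297) and with each sequence counted once (0.10). In p no V gene passed (0, with 3 at an unadjusted p under 0.05 and 0 by DESeq2), with IGHV1-26 at 0.77 ± 0.29, IGHV1-81 at 0.77 ± 0.34 and IGHV2-3 at −0.72 ± 0.31 (adjusted p = 0.139, 0.140 and 0.140). The most used V genes were IGHV8-12 (7.47%), IGHV5-6 (6.19%) and IGHV1-64 (5.84%) in n at day 7, IGHV8-12 (7.74%), IGHV2-3 (6.76%) and IGHV1-76 (6.27%) in p at day 7. At day 13 they were IGHV1-64 (5.60%), IGHV1-81 (4.81%) and IGHV6-3 (4.22%) in n, and IGHV1-26 (6.55%), IGHV5-6 (5.81%) and IGHV1-76 (5.50%) in p. At day 7 the count of 5 became 2 without p 3 and 3 without p 4. For IGHV1-81 in n, 0 V genes passed without day 7 n 3, day 13 n 1 or n 3. It was 2 without day 7 n 2 or n 4 or day 13 n 4. In p it was 2 without day 7 p 1 or day 13 p 2, and 1 without day 13 p 1 or p 4. A later test without rearrangements of both days gave 5 in p, 2 in n and 3 for p against n at day 7.

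**Figure D4:**
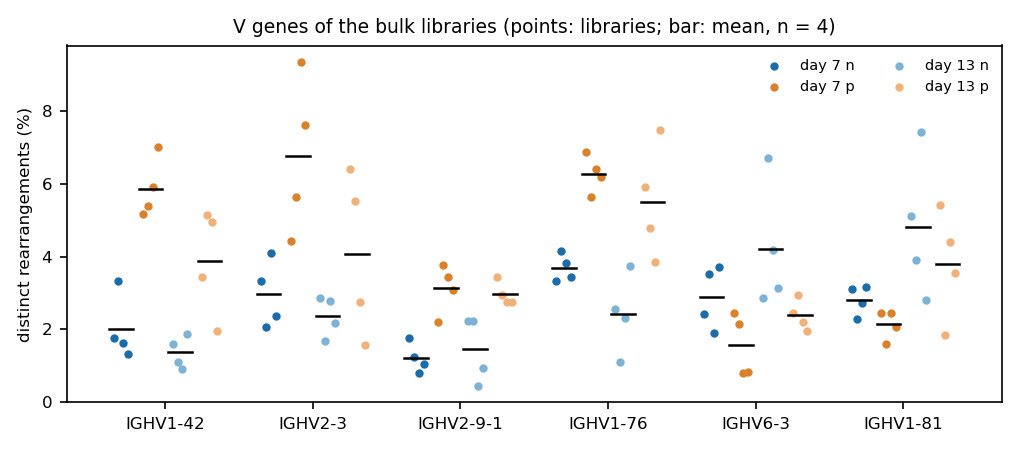
Percent of distinct rearrangements that use each of 6 V genes in each bulk library of n and p at days 7 and 13; points are libraries and bars their means, n = 4. IGHV1-42 averages 5.86% in p and 2.01% in n at day 7.

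Bulk heavy chains were matched to those of OVA 1 cells by V gene and CDR3 amino acid sequence. The matched share of these distinct sequences was 1.03% ± 0.533 in p and 0.557% ± 0.172 in n at day 7 (exact permutation p = 0.20). At day 13 it was 1.37% ± 0.394 and 0.361% ± 0.465 (exact p = 0.0571), with n = 4 each and 0 to 6 matches per library. With any V gene allowed, p exceeded n by 0.952 points at day 7 and 1.82 at day 13 (unadjusted exact p = 0.0286 each). With sign flips within the day 7 pairs the p was 0.125.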

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

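The tests of day 13 p 2 as a whole day 7 library, of molecules carried over from day 7 p 2, of genes that escape X inactivation and of cluster shares in expanded clones were set before their results were seen, the X test only after Xist had been seen. The other tests in this part, the splits of the samples included, were chosen only after the result was seen.

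A single library lay far from the other 3 of its group in 4 cases. The switched share of day 7 n 3 was 36.7%, and the others lay between 33.1% and 33.6%. The CDR3 length of day 7 p 2 was 12 amino acids, and the others were at 12.2. Clone evenness was 0.784 in day 13 n 2, with the others between 0.973 and 0.984, and 0.792 in day 13 p 2, with the others between 0.959 and 0.980. With 28 groups tested, chance alone picks out about 1 in 20. The p minus n difference in switched share was 12.7 percentage points larger at day 13 than at day 7 (exact permutation of labels within days, p = 0.0294, adjusted p = 0.0918).

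The bulk libraries day 7 p 2 and day 13 p 2 shared 165 rearrangements, and the median over 64 pairs of libraries from different days was 3. Independent origin in different mice is argued against by these 165. That day 13 p 2 is as a whole a day 7 library is argued against by its rearrangements absent from day 7, with 2.44 V mutations on average, since the highest day 7 p library had 1.11. Its rearrangements found in day 7 carried 1.04. Those of day 13 p 1, p 3 and p 4 carried 1.28, 1.02 and 1.47, so 1.04 does not single out p 2. The pair shared 72 identical sequences, so carry-over stays open. Clones of the same spleen cannot span both days. Rearrangements found on the other day made up 70.6% of day 13 p 2 and 48.4% of day 7 p 2, and also 33.0% of day 7 n 1, 30.5% of day 13 p 1 and 29.9% of day 13 p 4, and no biological explanation was tested.

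In OVA 1, 92.5% of cells had an Xist UMI and no UMI of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d or Uty was read, and in NP 1 and NP 2 it was the reverse. The labels give males for all libraries. A swap with an NP library is argued against by the 8.04% of OVA 1 cells with IGHV1-72. The X-linked genes Ddx3x, Eif2s3x, Kdm5c and Kdm6a escape X inactivation. Their median log2 ratio to OVA 1 was −0.37 in NP 1 and −0.66 in NP 2. Ddx3x was higher in NP 1 (0.38), so by the bound set these do not decide. By Xist and the Y-linked genes, sex goes with antigen, gate and library.

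Expanded clones held fewer memory-like cells than clones seen once. Without the memory-like cluster the median over genes of the ratio to the fold with it was 0.858, 0.866 and 0.699 (NP 1, NP 2 and OVA 1; 488, 453 and 533 of the 574 genes, those with an absolute log2 fold of at least 0.1), which argues against these cells as the whole cause, though the median fall in OVA 1 went from −0.35 to −0.20. With equal cluster weights in both arms it was 0.395, 0.358 and 0.359, so different cluster shares may account for part of the folds. Whether they are the whole cause cannot be told apart from a change within clusters, as these ratios lie between the bounds set for each. A biological difference that goes with clonal expansion stays open.

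The arms of a library are pairs, and 4 of the 10 splits of the 6 sums part them in every library as the real split does, too few for a share under 0.05. The real split gave 574 genes for expanded clones (highest other 1), 551 for switched cells (0), 152 for detected Myc (6) and 162 list genes for clusters 1, 3 and 10 against DZ-like cells (0), and 1 split reached each count. The other 6 splits keep both arms of a library together and gave at most 28, 6, 10 and 0. For p against n at day 7, where the replicate numbers pair the libraries, 8 splits part all 4 pairs as the real one does, too few for a share under 0.05. The real split gave 5 V genes (highest other 2), and 1 split reached this count; the other 27 splits part 2 pairs or none (highest 2). In the unpaired bulk comparisons 1 of 35 splits gave as many V genes as day 13 against day 7 in n (1 V gene, highest other 0). That share is under 0.05, but 1 V gene against 0 is too little to exclude chance. The call also ended with no low-count filter, each sequence counted once, or without day 7 n 3, day 13 n 1 or day 13 n 3. For p against n at day 13 and for day 13 against day 7 in p edgeR called 0 V genes (4 and 3 at an unadjusted p under 0.05, and 0 by DESeq2), a count that 35 of 35 splits reach by construction (highest other 2), so the splits decide nothing there.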

How the results depend on the processing

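Tests chosen only after the results were seen were those at up to 20% mitochondrial UMIs, without the memory-like, myeloid-like and T cell-like clusters and clusters 5, 13 and 16, and without cells of more than 1 heavy chain. So were comparisons without cluster 3, bulk data without rearrangements found on both days, thinned bulk sequences, and clusters 10 and 12. Where a value below differs from the reported one, the cause was not tested.

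The counts of genes moved most. DESeq2 called 30 genes for NP against OVA (238 by edgeR), 69 for expanded clones (574), 98 for switched cells (551), 55 for detected Myc (152) and 4 for IGHV1-72 lambda (73). Without the library block edgeR called 0 genes for expanded clones (93 at an unadjusted p under 0.05), 0 for switched cells (232), 0 for IGHV1-72 lambda (61), 3 for detected Myc. Without it 66 list genes passed for clusters 1, 3 and 10 against DZ-like cells (162) and 48 for cluster 10 against clusters 1 and 3 (134). For NP against OVA, 144 genes passed with no low-count filter, 153 with thinned cells, 76 in LZ-like cells, 139 in DZ-like cells, 147 at up to 20% mitochondrial UMIs and 134 without the clusters named above. For expanded clones, 320 passed with the strict cell filter, 303 with thinned cells, 1 in LZ-like cells, 7 in DZ-like cells, 186 without those clusters and 362 with clones by amino acid CDR3. For switched cells, 288 passed with thinned cells, 293 in LZ-like cells, 78 in DZ-like cells and 338 without those clusters. For detected Myc, 83 passed with the strict filter, 2383 with all UMIs of each cell and 4 in DZ-like cells. For IGHV1-72 lambda, 25 passed with thinned cells, 1 in LZ-like cells, 10 in DZ-like cells and 18 without those clusters.

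Leaving out a library gave 254 to 370 genes for expanded clones (370 without NP 1, 366 without NP 2 and 254 without OVA 1), 225 to 595 for switched cells (225 without NP 1, 277 without OVA 1), and 71 to 169 for detected Myc (71 without NP 1). List genes numbered 140 to 156 for clusters 1, 3 and 10 against DZ-like cells, 115 to 129 for cluster 10 and 137 to 161 for cluster 12. It was not run for NP against OVA and IGHV1-72 lambda, which keep no residual degrees of freedom.

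In the bulk data, p against n at day 7 gave 5 V genes, 3 with each sequence counted once, 3 without rearrangements of both days, and 2 to 6 when a library was left out (2 without p 3, 3 without p 4). At day 13 edgeR gave 0, 3 with no low-count filter and 1 without rearrangements of both days. Day 13 against day 7 in p gave 0, 5 without rearrangements of both days, and 0 to 2 with a library left out (2 without day 7 p 1 or day 13 p 2, 1 without day 13 p 1 or p 4). In n it gave 1, 2 with no low-count filter, 0 with each sequence counted once (4 at an unadjusted p under 0.05), 2 without rearrangements of both days, and 0 to 2 with a library left out (0 without day 7 n 3, day 13 n 1 or n 3, and 2 without day 7 n 2 or n 4 or day 13 n 4). With the replicate number as a block the counts were 5, 0, 0 and 1, so it changed no count. With sign flips within the numbers as pairs, the lowest adjusted p of the repertoire measures was 0.25, and none had passed without them. Same-numbered libraries deviated together with r of 0.18, 0.39, 0.56 and −0.31 at day 7 and −0.16, 0.09, 0.21 and −0.21 at day 13, and not every library correlated best with its own number. At day 7 the numbers were still taken as pairs, since same-numbered libraries shared 38 to 48 rearrangements and other libraries of that day 0 to 5; at day 13 they shared 4 to 18 against 1 to 19, and the numbers were not taken as pairs.

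The overlap with single-cell CDR3s, p minus n, had an unadjusted exact p of 0.0286 with any V gene allowed, at 0.952 percentage points for day 7 and 1.82 for day 13. With sign flips within the day 7 pairs the p was 0.125, which did not pass. Among cells in the gene table with 1 heavy and 1 light chain, lambda among IGHV1-72 cells was 97.7% in NP 1 and 99.3% in NP 2, and tyrosine at CDR3 position 4 in OVA 1 was 0%. At resolution 0.5 DZ-like shares were 24.2%, 23.5% and 19.5%, and LZ-like shares 33.2%, 32.3% and 35.2% (NP 1, NP 2 and OVA 1).

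Direction turned for these named genes, given as log2 folds. For expanded clones in LZ-like cells Sgo1 was at −0.64, Cep55 at −0.23, Cd83 at 0.0186, Nfkbia at 0.0128, Ccr6 at 0.0946, Srm at 0.0329 and Atp5a1 at −0.0150. In DZ-like cells Rps27 was at 0.000449, Ptma at −0.0335, Mcm5 at −0.0111 and Rrm1 at −0.0117. For IGHV1-72 lambda in LZ-like cells Hist1h2ae was at −0.52, Hist1h1b at −0.36, Klf2 at 0.76 (0.37 without the clusters named above), Ly6d at 0.0495, Hbb-bs at −0.53 and Cd55 at 0.30. In DZ-like cells Hmgb2 was at −0.0194. Without those clusters Cd3d was at 0.87 for NP against OVA, and for detected Myc S100a9 was at 0.13 and S100a8 at 0.22. For detected Myc in LZ-like cells Mki67 was at 0.25.

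The direction of the list test, which can differ from the sign of the median, turned for the lists below, given with their medians. They were, for NP against OVA, erythroid markers at −0.98 with the strict filter (passing downward, adjusted p = 0.00762) and T cell markers at 0.35 without those clusters. For expanded clones they were the receptor and NF-kB response at 0.0503 and myeloid markers at 0.27 in LZ-like cells. Myeloid markers were at 0.0729 and S phase at −0.0796 in DZ-like cells (passing downward, 0.000536), and myeloid markers at 0.10 without those clusters. For switched cells they were the receptor response at −0.14 in LZ-like cells (passing downward, 8.7e-05), the ribosome at −0.00403 in DZ-like cells, and MYC targets at 0.00897 for IgG1. With a library left out the ribosome lay between −0.0439 and 0.00356, the latter without OVA 1. For detected Myc in LZ-like cells they were G2 and M phase at 0.19 (passing upward, 0.00148), memory genes at −0.17 and nuclear OXPHOS at 0.00385. Memory genes were at −0.32 in DZ-like cells. With all UMIs memory genes were at −0.15, nuclear OXPHOS at 0.13 (passing upward, 7.7e-11), hypermutation genes at 0.19 (0.0417) and the TCA cycle at 0.11 (0.00332). For IGHV1-72 lambda in LZ-like cells they were the receptor response at 0.0390, the ribosome at 0.0151, erythroid markers at −0.46, memory genes at 0.00649 and plasma cell genes at 0.0327. In DZ-like cells G2 and M phase was at −0.0180 (passing downward, 0.0247). For cluster 10 it was nuclear OXPHOS, at −0.0441 without cluster 3.

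Of 562 alternative comparison results, 491 stayed within their bounds. Bulk repertoire measures counted as within even where the sign turned. Of 3510 named gene and V gene values, 2722 kept direction and threshold side, 748 lost only the threshold and 17 gained it. Of 1135 list values, 923 kept both, 155 lost the threshold and 31 gained it. Depth limits the Myc comparison, as unthinned detection rose with UMIs per cell. Comparing cells by mutation load, weighting by reads or molecules, and keeping sequences with at least 2 of either were not run, as neither was given.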

Other observations

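All tests in this part, on clusters 10 and 12, were chosen only after the clusters were seen.

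Cluster 12, small and unnamed, had 3.12%, 3.09% and 2.39% of cells in NP 1, NP 2 and OVA 1. It was compared with clusters 1, 3 and 10 over the metabolic lists. Nuclear-encoded OXPHOS genes were higher, with 63 of 77 past the threshold upward and 2 downward (66 and 2 adjusted over the list alone; median log2 fold 0.60), among them the electron carrier Cycs at 1.56 ± 0.10 (SE) and the ATP synthase gene Atp5g1 at 1.21 ± 0.09. The list test gave an adjusted p of 1.4e-14, and 0.395 with an estimated correlation. MYC targets rose in 33 of 34 cases (34 adjusted over the list alone; median 1.30; adjusted p = 1.1e-38, and 0.219 with an estimated correlation), with the transport GTPase Ran at 1.95 ± 0.08, the chaperone Hspd1 at 2.06 ± 0.10 and Srm at 2.13 ± 0.11. Myc itself was at 0.26 ± 0.13 (edgeR adjusted p = 0.0847). TCA cycle genes rose in 11 of 16 cases (12 adjusted over the list alone; median 0.47; adjusted p = 0.00311, and 0.234 with an estimated correlation), with Idh3a at 1.38 ± 0.13. Glycolysis genes rose in 9 of 16 cases (11 adjusted over the list alone; median 0.52; adjusted p = 3.3e-05, and 0.247 with an estimated correlation), with Ldha at 1.33 ± 0.08. In the mTORC1 and amino acid list 9 of 17 rose and 2 fell (9 and 3 adjusted over the list alone; adjusted p = 0.00489, and 0.219 with an estimated correlation), with the serine synthesis gene Phgdh at 1.56 ± 0.10 and Ddit4 at −1.36 ± 0.17. Mitochondrially encoded genes fell in 9 of 13 cases (9 adjusted over the list alone; median −0.32; adjusted p = 0.00130, and 0.389 with an estimated correlation), with mt-Co1 at −0.75 ± 0.07. The ribosome list had 16 of 44 higher and 5 lower (16 and 5 adjusted over the list alone; adjusted p = 0.235). By edgeR's test with library as a block 158 of 216 list genes passed, 140 higher and 18 lower, and 116 with thinned cells. Against the LZ-like clusters 1 and 10 alone it was 150 of 215, and nuclear OXPHOS (median 0.48), MYC targets (1.04), the TCA cycle (0.40), glycolysis (0.48) and mitochondrially encoded genes (−0.29) were still called, but mTORC1 was not (adjusted p = 0.0718) and the ribosome was (0.0211). Median depth in the cluster was 11998, 12943.5 and 14532 UMIs, above that of the clusters it was compared with, and doublets were not removed.

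Cluster 10, the LZ-like cluster led by Myc and receptor response genes, was compared likewise with clusters 1 and 3. All 34 of 34 MYC targets rose (34 adjusted over the list alone; median 1.12; adjusted p = 2.1e-79, and 0.190 with an estimated correlation), with Myc at 3.66 ± 0.15, the polyamine enzyme Srm at 2.46 ± 0.12 and Nolc1 at 2.26 ± 0.10. In the mTORC1 and amino acid list 14 of 17 rose and 2 fell (14 and 2 adjusted over the list alone; adjusted p = 5.4e-07, and 0.282 with an estimated correlation), with the amino acid transporter Slc7a5 at 1.92 ± 0.17 and Ddit4 at −1.59 ± 0.12. Glycolysis had 10 of 15 higher and 1 lower (11 and 1 adjusted over the list alone; adjusted p = 3.1e-06, and 0.278 with an estimated correlation), with Ldha at 0.99 ± 0.05. Ribosomal genes fell in 33 of 44 cases and rose in 2 (34 and 2 adjusted over the list alone; median −0.15; adjusted p = 1.2e-08, and 0.282 with an estimated correlation), with Rps27 at −0.37 ± 0.04. Mitochondrially encoded genes fell in 10 of 13 cases (10 adjusted over the list alone; median −0.16; adjusted p = 0.000956, and 0.550 with an estimated correlation), with mt-Co1 at −0.29 ± 0.03. Nuclear-encoded OXPHOS had 23 of 77 higher and 3 lower (23 and 3 adjusted over the list alone; median 0.12; adjusted p = 0.0120, 0.0574 without OVA 1, and 0.572 with an estimated correlation), with Cycs at 0.96 ± 0.09. The TCA cycle had 3 of 16 higher (3 adjusted over the list alone; adjusted p = 0.327). By edgeR's test with library as a block 134 of 215 list genes passed, 85 higher and 49 lower; 48 passed without the block and 107 with thinned cells. Against cluster 1 alone it was 103 of 215, and nuclear OXPHOS was not called and turned (median −0.04, adjusted p = 0.316), while MYC targets (1.02), mTORC1 (0.62), glycolysis (0.25), the ribosome (−0.10) and mitochondrially encoded genes (−0.11) were still called.

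Of the 10 splits of the 6 sums of either comparison, 4 part the arms of every library, too few for a share under 0.05. The real split gave 134 list genes for cluster 10 and 158 for cluster 12, the highest other 0 in both, and 1 split reached each.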
